A study of Mus musculus with 4 samples.

How the data were processed

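RNA was measured by 10x Genomics droplet single-cell sequencing of polyadenylated transcripts in 4 libraries, 2 from C57BL/6J mice on a control diet and 2 from mice on the Amylin liver NASH model diet. Per the labels, livers were perfused and digested with Liberase in the presence of flavopiridol, an inhibitor of transcription that limits changes during digestion. Hepatocytes were removed by slow spins, non-parenchymal cells were taken through Percoll and OptiPrep gradients and red cells were lysed, and CD45+ CD146- cells were sorted. The labels do not state whether each library came from a separate mouse or which libraries were processed on a shared day.

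The deposited values are counts, raw UMI numbers per gene and cell, for 27998 genes and 6927 barcodes in 4 matrices. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mm10 build, without versions or a role for each tool. How barcodes were called as cells, any filter before deposit and whether reads were counted by strand are not given in the sources used here. Gene identifiers were matched to GENCODE vM21 (mm10), where 27645 of 27998 (98.74%) were found. Constant genes of immunoglobulins and T cell receptors are absent from the gene table. Barcodes shared between libraries numbered 2 to 8 per pair, against 3.45 to 4.73 by chance, and no library held signals of both sexes.

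Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. In each library the cells with the highest Scrublet scores were left out as putative doublets, at 0.8% per 1000 cells, which removed 14, 17, 20 and 28 cells. Counts were scaled to 10000 per cell and log-transformed. Scanpy 1.11.5 took 2000 variable genes, 30 principal components and 15 nearest neighbours, and Leiden clusters were drawn at resolution 1.0 with igraph 0.11.9. Libraries were not integrated, since each library lies within 1 diet. The other tools were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 under Python 3.11.15.

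Clusters were named from marker lists written in advance. A cluster took the class with the most markers among its top 10 genes by fold against other cells, with at least 2 such markers, no tie and at least 3 markers each detected in at least 25% of cells. This rule was changed after the clusters had been seen and before any comparison between diets, since macrophages are most of the cells and hide their own markers. In the changed rule a cluster in which C1qa, C1qb and C1qc each had a UMI in at least 90% of cells was called macrophage-like if at least 3 macrophage markers were detected and fewer than 2 of its top 10 genes marked another lineage, and was otherwise left unnamed. Genes of the Kupffer identity list were not counted as marking another lineage, and a C1q-high cluster led by cell cycle genes was named cycling, so the cycling class (282 cells) is a C1q-high cluster. Macrophage-like clusters with UMIs of Clec4f and of Vsig4 in at least 80% of cells were called Kupffer-like, so the Kupffer markers are selected on in that class.

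Counts were summed per library and class, and classes with at least 10 cells in each library were tested. EdgeR 4.0.16 with limma 3.58.1 under R 4.3.3 was used with TMM factors, filterByExpr and the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Shares of classes with at least 10 cells were tested with the same model on numbers of cells, with the kept cells as offset. The interaction was fitted on macrophage-like and monocyte-like sums with the library as block. Each value carries 2 libraries per diet, an exact permutation test of 2 against 2 cannot go below p = 0.333, and such groups are too small for a test of other splits of the samples. Folds against a group with 0 UMIs were computed against a floor of 3 counts over the group, and ratios with 1 to 3 UMIs carry a 95% counting interval.

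Of 30 gene lists written in advance, those with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. A list of glucocorticoid response genes was added after the data had been seen.

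The genes named were set by a rule. They are the 12 largest positive and 12 largest negative log2 fold changes in macrophage-like, Kupffer-like and monocyte-like cells, and 5 each way in other classes, among genes past the threshold with separated libraries and at least 50 CPM in the higher group. They also include the 4 members with the smallest p of each list, the 8 interaction genes with the smallest adjusted p and, in macrophage-like cells, Timd4, Clec4f, Cd163, Marco, Trem2, Gpnmb, Spp1, Cd9, Ccr2, Cx3cr1 and Ly6c2. Mitochondrial, ribosomal protein, Gm-numbered, Rik and receptor variable genes were counted and not named. The text names a part of the genes that met this rule. A result withheld for evaluation is not reported here. Groups, tests, lists and this rule were set before the data were examined, apart from the changes stated here.

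The calls were tested on simulated data in which 200 genes were changed. Of these, 62.5% were recovered at 2-fold and 96% at 4-fold in macrophage-like, 63.5% and 92.5% in Kupffer-like, 44.5% and 85.5% in B cell-like and 24.5% and 89% in T cell-like sums. False calls were 1.16% to 6.32% of the calls in these classes. The interaction recovered 15% at 4-fold and 48.5% at 16-fold. Camera recovered 26 of 26 lists moved 2-fold at the preset correlation and 1 with an estimated correlation, so a list that misses with an estimated correlation is weak evidence. Genes were simulated independently, so the recovery at the preset correlation does not cover lists whose genes vary together. With 200 genes changed, against 4527 of 10335 called in the real macrophage-like sums, the simulation does not cover such wide change either.

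Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter and a stricter filter (50 counts in 2 libraries) on genes, each library left out, the replicate number as block, no doublet removal and 3 times as many putative doublets, a stricter cell filter (500 genes, 5% mitochondrial UMIs), Leiden at 0.5 and 2.0, assignment cell by cell by marker list, thinning to 1000 UMIs with equal cells, and shares thinned to 2000 UMIs. Chosen after seeing the data were the tests with all deposited cells, without the Mmp13-led cluster, without B cell-like cells carrying the C1q signal, with fewer than 10 cells allowed, and in 3 more classes. The cell-by-cell alternative has flaws. Its platelet list holds Clec1b and Pf4, which macrophages also express. Its macrophage list holds Clec4f and Marco and its monocyte list Ccr2 and Ly6c2, so these genes are selected on under it.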

Results

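Droplet single-cell RNA libraries were made from non-parenchymal liver cells of C57BL/6J mice, sorted for the leukocyte marker CD45 and against CD146, a marker of endothelial cells. The sort sets which cell types could be seen and in which proportion. There were 2 libraries from mice on a control diet and 2 from mice on the Amylin liver NASH model diet. The diet is used to bring about nonalcoholic steatohepatitis (NASH), in which the liver stores fat, becomes inflamed and scars. The study's title places its question in how myeloid cells of the liver, the macrophages, monocytes and dendritic cells, change their program and diversify in NASH. The labels do not say that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical.

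The deposited barcodes numbered 1550 and 1805 in the control libraries 1 and 2, and 1639 and 1933 in the NASH libraries 1 and 2. They held 5513953, 5684819, 13749657 and 15619962 unique molecular identifiers (UMIs, one count per captured transcript). The median was 3064.5 and 2573 UMIs per barcode in the control libraries and 7447 and 7344 in the NASH libraries. The median share of mitochondrial UMIs was 6.43% and 6.23% in the control libraries and 3.43% and 3.21% in the NASH libraries. Filters on detected genes and mitochondrial share removed 14.8% and 20.4% of the control barcodes and 2.87% and 2.38% of the NASH barcodes. After removal of putative doublets 1307, 1420, 1572 and 1859 cells were kept, 6158 in all. Macrophage-like cells, the most numerous class, gave 986, 872, 742 and 1033 cells with medians of 3173, 2846, 8292 and 7620 UMIs.

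The first comparison asked which cell classes differed in share between the diets. Monocyte-like cells, the circulating precursors of recruited macrophages, made up 0.540% ± 0.331 (SD, n = 2) of kept cells in the control libraries and 9.27% ± 2.91 in the NASH libraries, a log2 ratio of 4.06 (SE 0.693). Dendritic cell-like cells, which present antigen to T cells, rose from 1.37% ± 0.957 to 10.2% ± 2.36, a log2 ratio of 2.88 (SE 0.626). Plasmacytoid dendritic cell-like cells, known for making type I interferon, fell from 8.96% ± 4.56 to 2.93% ± 0.264, a log2 ratio of -1.61 (SE 0.581). Cholangiocyte-like cells, which line bile ducts, were 0 of 1307 and 0 of 1420 control cells, with exact 95% upper limits of 0.282% and 0.259%. They were 0.514% ± 0.187 of NASH cells, with 6 and 12 cells. These 4 of the 14 classes tested passed edgeR's quasi-likelihood test on numbers of cells with Benjamini-Hochberg adjustment. The adjusted p in this edgeR test was 3.72e-05 for monocyte-like, 0.000579 for dendritic cell-like, 0.0339 for plasmacytoid dendritic cell-like and 0.00795 for cholangiocyte-like cells.

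Macrophage-like cells held 68.4% ± 9.92 of the control cells and 51.4% ± 5.92 of the NASH cells, and this difference did not pass the same edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.526). Endothelial-like, T cell-like, NK cell or ILC1-like, neutrophil-like, stellate or fibroblast-like, plasma cell-like, cycling, hepatocyte-like and B cell-like shares did not pass either, at adjusted p from 0.206 to 0.779 in that test. Endothelial-like shares did pass as lower in NASH under 5 alternatives (adjusted p from 0.00261 to 0.0345). These were 3 times as many putative doublets removed, the stricter cell filter, Leiden resolution 2.0, assignment cell by cell and the denominator without macrophage-like cells. T cell-like shares passed as higher at resolution 0.5 (0.0118) and cell by cell (0.00862), and neutrophil-like shares with more doublets removed (0.0253) and the stricter filter (0.0146). Assignment cell by cell also gave calls for macrophage-like (0.026), NK cell or ILC1-like (0.0111) and stellate or fibroblast-like shares (0.0172). T cell-like cells were 1.41% ± 0.799 and 2.89% ± 0.136, and B cell-like cells 3.54% ± 0.570 and 3.96% ± 1.55, of control and NASH cells. Clusters kept out of every class by the naming rule, which was set after the clusters were seen, held 2.15% ± 0.644 of control and 6.24% ± 1.07 of NASH cells. The largest of them (cluster 18), C1q-high and led by T cell genes, held 0.623% ± 0.0154 of control and 4.51% ± 0.905 of NASH cells. The T cell-like share does not include it. Per library, monocyte-like cells were 0.306% and 0.775% in the control libraries (exact Clopper-Pearson 95% intervals 0.0834 to 0.782% and 0.387 to 1.38%) and 11.3% and 7.21% in the NASH libraries (9.80 to 12.99% and 6.07 to 8.48%). These intervals cover counting error only, and the sort and the unequal filter losses above can set any of these shares. Leaving out a control library ended every call (monocyte-like adjusted p = 0.0870 without control 1 and 0.0781 without control 2), with 1 control library left against 2. The log2 ratios were then 3.56 and 4.88 for monocyte-like, 2.31 and 3.87 for dendritic cell-like and -2.06 and -0.97 for plasmacytoid dendritic cell-like cells. Cholangiocyte-like cells were 0 in both control libraries, so no ratio is given for them. Leaving out NASH library 1 or 2 left only the monocyte-like call, at adjusted p = 0.0498 or 0.0169 in edgeR's quasi-likelihood test. The plasmacytoid dendritic cell-like call was also lost with all deposited cells (adjusted p = 0.081) and with cells assigned one at a time (0.0693), and the cholangiocyte-like call with the stricter cell filter (0.0581). That filter also lowered the log2 ratio to 2.02 for monocyte-like and 1.58 for dendritic cell-like cells and moved it to -2.48 for plasmacytoid dendritic cell-like cells.

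**Figure D1:**
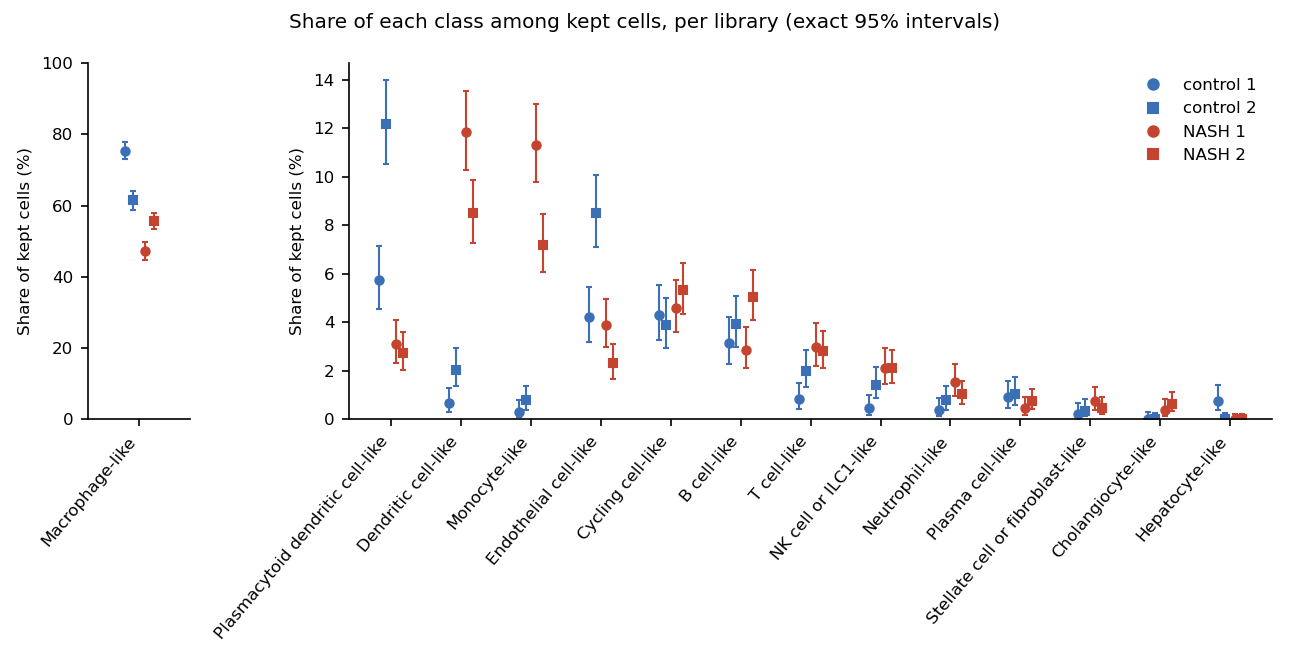
Share of each class among kept cells (percent, vertical axes) for the 2 control libraries (blue) and the 2 NASH libraries (red), with exact Clopper-Pearson 95% intervals as bars. Monocyte-like cells were 0.306% and 0.775% of the control and 11.3% and 7.21% of the NASH libraries, and macrophage-like cells have an axis of their own.

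The main comparison asked how liver macrophages as a class differed between the diets. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.897 ± 0.547 to 298 ± 103 CPM, counts scaled to the class total (mean ± SD, n = 2), a log2 fold change of 8.40 (SE 0.433). Spp1 (osteopontin) rose from 1.60 ± 0.459 to 347 ± 222 CPM, and Mmp12, a macrophage elastase, from 14.5 ± 3.13 to 917 ± 88.4 CPM. Trem2, a lipid-sensing receptor, rose from 52.4 ± 8.04 to 1068 ± 126 CPM (log2 4.35, SE 0.183), and the tetraspanins Cd9 and Cd63 reached log2 fold changes of 5.52 and 5.87. Cd163, the receptor for hemoglobin bound to haptoglobin, fell from 1271 ± 6.07 to 7.45 ± 5.03 CPM, a log2 fold change of -7.37 (SE 0.489). Timd4, a phosphatidylserine receptor of long-resident Kupffer cells, fell from 412 ± 44.0 to 63.9 ± 21.1 CPM (log2 -2.68, SE 0.225).

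Of 10335 genes tested in macrophage-like sums, 4527 changed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these 2373 were higher and 2154 lower in NASH. The adjusted p in this test was 2.80e-05 for Gpnmb, 0.0122 for Spp1, 1.85e-07 for Mmp12, 5.41e-07 for Trem2, 1.54e-06 for Cd9, 0.000582 for Cd63, 0.000447 for Cd163 and 7.53e-05 for Timd4. The naming rule, met by 1904 genes, also took among the genes that rose Gdf3, H2-M2, Fabp5, Mmp13, Itgax and Olfml3. Their log2 fold changes other than that of Gdf3 ran from 4.33 (Olfml3) to 5.92 (H2-M2). Gdf3 had 3 UMIs in the control and 896 in the NASH libraries, a ratio of 125 at equal depth (95% counting interval 42.5 to 606). The genes that fell by this rule included the complement genes C2 (log2 -5.27), C4b (-3.51), C6 (-2.60) and the leptin receptor Lepr (-3.11). Also lower were the hepatocyte transcripts Mup3 (-3.88) and Apoa1 (-2.65), and Abhd11os (-5.61), Ets2 (-2.57), Jdp2 (-2.40) and Ptprm (-2.39). C4b and Mup3 have near-identical copies (C4a, the other Mup genes) and Abhd11os is antisense to Abhd11, so their counts are uncertain.

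Clec4f, the C-type lectin that marks Kupffer cells, fell from 3884 ± 263 to 2647 ± 560 CPM (log2 -0.55, SE 0.169, adjusted p = 0.0218 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccr2, the receptor that draws monocytes into tissue, rose from 11.2 ± 0.816 to 102.1 ± 10.96 CPM (log2 3.18, SE 0.175), and the fractalkine receptor Cx3cr1 from 23.3 ± 15.6 to 290 ± 5.92 CPM (log2 3.67, SE 0.504). The scavenger receptor Marco stood at 494 and 3170 CPM in the control libraries and at 22.5 and 24.3 CPM in the NASH libraries, and with that spread it did not pass (log2 -6.29, SE 1.53, adjusted p = 0.0884 in edgeR's test). Ly6c2, a marker of inflammatory monocytes, stood at 19.3 ± 4.51 and 28.5 ± 6.69 CPM and did not pass (log2 0.57, adjusted p = 0.0665 in edgeR's test). In the mm10 annotation (GENCODE vM21) these are protein-coding genes. Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036546 to 49070929, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050 and Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147. Cd9 (ENSMUSG00000030342, 125460266 to 125494791), Cd163 (ENSMUSG00000008845, 124304656 to 124330527) and Clec4f (ENSMUSG00000014542, 83644542 to 83656187) also lie on chromosome 6. Timd4 (ENSMUSG00000055546) lies on chromosome 11 from 46810800 to 46844332 and Marco (ENSMUSG00000026390) on chromosome 1 from 120474538 to 120505024.

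Different clusters held most of the class under each diet. Control macrophage-like cells lay mainly in a cluster led by Marco, Cxcl13 and Hmox1 (158 and 718 cells of the control libraries 1 and 2) and one led by Fkbp5, Abhd11os and Fosb (792 and 80 cells), which together held 5 and 7 cells of the NASH libraries. NASH macrophage-like cells lay mainly in clusters led by Folr2, Apoc1 and Ccl24 (158 and 327 cells), by Mmp13, Mmp12 and Il1rn (267 and 296 cells) and by H2-M2, Cx3cr1 and Olfml3 (312 and 403 cells). The calls of Spp1, Gdf3, C4b and Lepr were lost without either control library, those of Fabp5 and Cx3cr1 without either NASH library, and that of Clec4f without control 1 or NASH 1. The log2 fold change of Clec4f was 0.06 when cells were assigned one at a time by their markers. Clec4f is one of the macrophage markers of that assignment, so this value is partly set by the selection. Marco passed without control 1, without control 2 and in DESeq2, and Ly6c2 was lower in NASH under 4 other cell assignments or filters (log2 from -0.73 to -0.09).

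**Figure D2:**
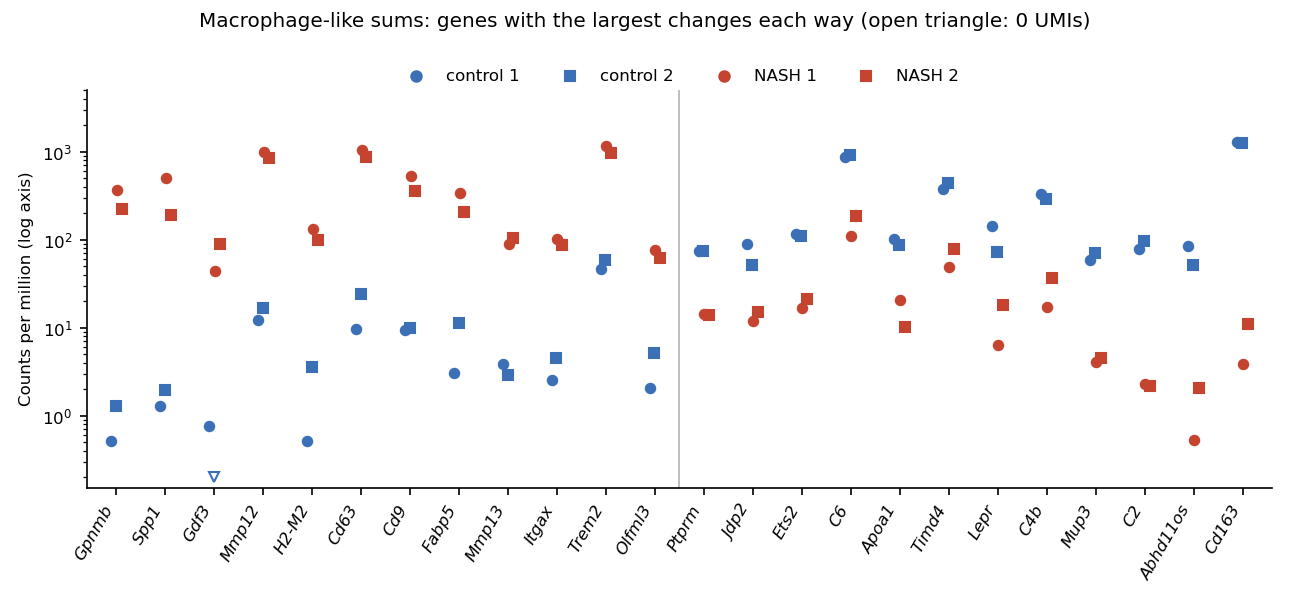
CPM in macrophage-like sums (log axis) for the 12 genes with the largest positive and the 12 with the largest negative log2 fold change under the naming rule, for the 2 control (blue) and 2 NASH (red) libraries, with an open triangle for 0 UMIs. Trem2 stood at 46.7 and 58.1 CPM in the control and at 1157 and 979 CPM in the NASH libraries, and Cd163 at 1275 and 1266 against 3.89 and 11.01 CPM.

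Gene lists fixed in advance moved together in macrophage-like sums. Of 25 measured members of the lipid- and scar-associated macrophage list, 23 rose and none fell (23 when adjusted over the list alone), with a median log2 fold change of 2.97. Mmp12, Trem2, Cd9 and Mmp13 had the smallest p. All 4 MHC class II genes with the smallest p rose about as far, H2-Eb1 from 1020 to 6243, H2-Ab1 from 1403 to 8576, H2-Aa from 1376 to 7877 and Cd74 from 3886 to 20450 CPM. In this antigen presentation list 11 of the 15 members rose and 1 fell (11 and 1 over the list alone). Of 26 interferon-stimulated genes 18 rose and none fell (21 adjusted over the list alone), such as Oas1a (log2 2.00) and Ifi44 (2.76). Of 29 genes of oxidative phosphorylation 27 rose (28 over the list alone), with a median of 0.86 and with Atp5g1 (1.503), Uqcrc1 (1.49), Sdhb (1.27) and Cox5b (1.19) as examples. The Kupffer identity list moved the other way, with 16 of 29 members lower and 4 higher (18 and 4 over the list alone), such as Slc40a1, the iron exporter (log2 -1.96), the mannose receptor Mrc1 (-1.76), Cdh5 (-1.64) and Timd4. Limma's camera test with a preset correlation and Benjamini-Hochberg adjustment gave adjusted p = 2.86e-15 for the lipid- and scar-associated, 2.06e-05 for the MHC class II, 4.48e-07 for the interferon, 2.47e-11 for the oxidative phosphorylation and 4.72e-05 for the Kupffer identity list. With an estimated correlation the adjusted p was 0.440, 0.491, 0.606, 0.440 and 0.508 for these lists, and 0 of the 11 lists that passed at the preset held.

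A further 4 lists of cell function passed camera at the preset correlation. Of 19 measured members of the monocyte and recruitment list 9 rose and 1 fell (9 and 1 over the list alone). Among those that rose were Ccr2, the protease Napsa (log2 2.45), the chemokine receptor Ccr1 (3.30) and Ms4a4c (2.54), at camera adjusted p = 0.00139 and adjusted p = 0.440 with an estimated correlation. Of 21 extracellular matrix and fibrosis mediators 10 rose and none fell (10 over the list alone), such as the urokinase receptor Plaur (1.99), Mmp2 (3.74) and the growth factor Pdgfa (1.43), at adjusted p = 0.00286 and adjusted p = 0.440 with an estimated correlation. Adam8 of this list had 2 UMIs in the control and 284 in the NASH libraries, a ratio of 59.3 (95% counting interval 16.3 to 492). Of 22 glycolysis and hypoxia genes 12 rose and 3 fell (12 and 3 over the list alone). The enzymes Ldha (1.75), Gapdh (1.85), Eno1 (1.99) and Pkm (1.43) rose, and the list stood at adjusted p = 0.0131 and adjusted p = 0.508 with an estimated correlation. The immediate-early and stress list fell, with 11 of 23 members lower and 3 higher (11 and 3 over the list alone), at adjusted p = 0.0456 and adjusted p = 0.725 with an estimated correlation. Junb fell from 520 to 166 CPM (-1.65), Dusp1 by 1.90 and Zfp36 by 1.30 on the log2 scale, while the heat shock gene Hsp90aa1 rose (1.07). This last call was lost without NASH library 1 (adjusted p = 0.292) and with upper-quartile factors (adjusted p = 0.0503).

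Markers of other cells moved in the same sums. Of 15 hepatocyte transcripts 12 fell and none rose (13 over the list alone), with a median log2 fold change of -1.71. Mup3, Apoa1, Cyp2e1 (-1.56) and Serpina1a (-1.96) had the smallest p, and the list stood at camera adjusted p = 9.03e-07 and adjusted p = 0.528 with an estimated correlation. Of 13 endothelial transcripts 7 fell (9 over the list alone), such as Lyve1 (-3.16), Ptprb (-1.67), Stab2 (-0.93) and Dnase1l3 (-0.80), at adjusted p = 0.00490 and adjusted p = 0.454 with an estimated correlation. CPM are scaled to the class total, and macrophage-like cells held 2.64 times as many UMIs in the NASH libraries (ratio of medians). Whether the hepatocyte and endothelial transcripts came from macrophages or were carried over from other cells was not tested. The erythroid and platelet list did not pass (camera adjusted p = 0.601, 1 of 5 higher). Its hemoglobin genes were spread between the control libraries, with Hba-a1 at 19.7 and 990 CPM there and at 20.3 and 22.0 CPM in the NASH libraries. Neutrophil RNA (camera adjusted p = 0.469, 5 higher and 2 lower of 9) and macrophage RNA (0.704, 5 and 3 of 11, median 0.24 and mean -0.15) did not pass.

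The other lists of cell function did not pass camera with Benjamini-Hochberg adjustment. Counts of members higher and lower in NASH were 7 and 4 of 18 for LXR targets and cholesterol efflux (adjusted p = 0.414), where Apoe rose from 12749 to 61531 CPM (log2 2.27). They were 6 and 1 of 19 for cholesterol biosynthesis (0.0740), 6 and 7 of 28 for lysosome and phagocytosis (0.582), 5 and 5 of 22 for fatty acid handling (0.4197) and 5 and 8 of 16 for complement (0.289). The inflammatory cytokine and NF-kB list went both ways, with 5 higher and 9 lower of 23 (adjusted p = 0.188). Its interleukin Il1b fell from 344 to 118 CPM (log2 -1.55) and Ier3 by 2.19 on the log2 scale, while the interleukin-1 receptor antagonist Il1rn rose from 41.7 to 146 CPM (1.80) and the chemokine Ccl12 rose by 3.53. Iron and heme genes numbered 5 higher and 4 lower of 14 (0.791, median 0.07 against a test direction of down), neutrophil maturation 9 and 5 of 21 (0.8004), B cell activation 4 and 5 of 18 (0.343, median -0.35 and mean 0.13), T and NK effector genes 6 and 2 of 11 (0.0614), naive lymphocyte genes 1 and 5 of 10 (0.0740) and cell cycle genes 7 and 1 of 17 (0.0614). The stellate, cholangiocyte, B cell and T and NK cell RNA lists had fewer than 5 measured members here and were not tested.

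**Figure D3:**
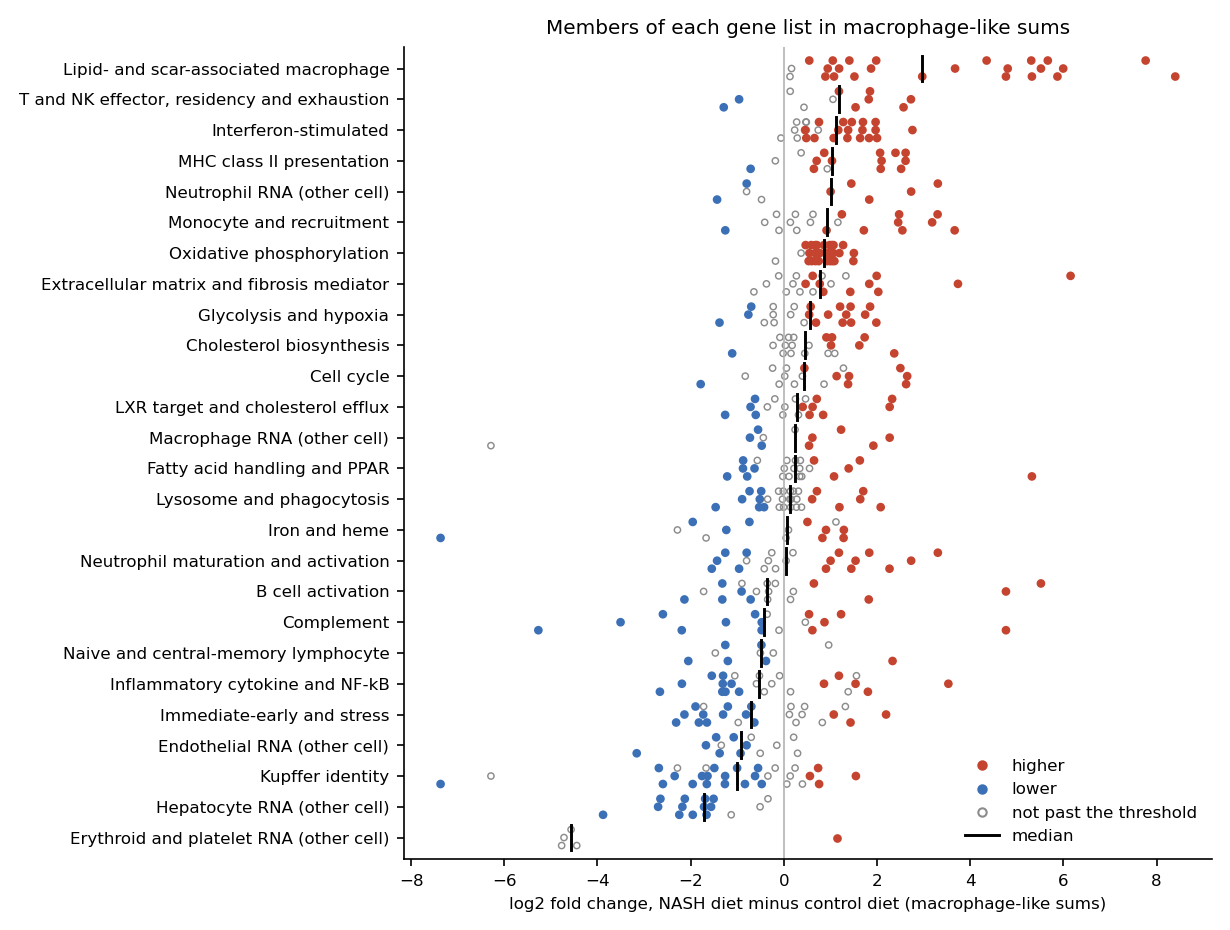
Log2 fold change (NASH minus control, horizontal axis) of each measured member of the 26 gene lists tested in macrophage-like sums, with red points higher, blue points lower and open points not past an adjusted p of 0.05, and a black bar at each list's median. The lipid- and scar-associated list has the highest median, 2.97, and the hepatocyte RNA list has 12 of 15 members lower.

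To state how many macrophage-like cells showed each readout at equal depth, every cell was thinned to 1000 UMIs, which left out 13 and 9 shallower control cells and 0 NASH cells. Cd163 had a UMI in 69.9% ± 3.09 (SD, n = 2) of control cells and 0.783% ± 0.536 of NASH cells. Timd4 went from 35.8% ± 0.281 to 4.55% ± 2.05 and Clec4f from 95.8% ± 2.52 to 56.7% ± 5.99. Trem2 went from 5.06% ± 1.199 to 52.1% ± 5.06, Cd9 from 0.868% ± 0.0805 to 28.2% ± 5.34, Gpnmb from 0.109% ± 0.00926 to 17.1% ± 5.63, Spp1 from 0.161% ± 0.0634 to 8.32% ± 3.28 and Ccr2 from 0.939% ± 0.311 to 7.04% ± 0.914. Both NASH libraries lay on the same side of both control libraries for all 8 genes, and the exact permutation test of 2 against 2 libraries gave p = 0.333 for each, the smallest it can give. Without thinning, the control and NASH shares were 87.7% and 3.54% for Cd163, 68.1% and 18.4% for Timd4, 98.3% and 74.8% for Clec4f, 13.1% and 92.4% for Trem2, 3.32% and 74.8% for Cd9, 0.273% and 45.5% for Gpnmb, 0.216% and 27.4% for Spp1 and 2.40% and 26.9% for Ccr2. With cells assigned one at a time, the NASH shares at 1000 UMIs were 86.9% for Clec4f, 9.11% for Timd4, 2.65% for Ccr2 and 3.44% for Spp1. Clec4f is on the macrophage list and Ccr2 on the monocyte list of that assignment, so their shares there are partly set by the selection.

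T cell-like cells gave a background at the same thinning for the genes other than Ccr2 and Cd9. Cd9 had a UMI in 3.57% ± 5.05 of control T cell-like cells, more than in control macrophage-like cells, so this class is no background for it. The NASH shares of T cell-like cells were 2.03% ± 0.145 for Trem2, 0% for Gpnmb and 2.03% ± 0.145 for Spp1. Their control shares were 0% for Cd163, 6.33% ± 3.90 for Timd4 and 12.7% ± 7.81 for Clec4f. An unnamed C1q-high cluster led by T cell genes (cluster 18, 81 and 72 NASH cells) was kept out of this class. These shares may thus understate carried-over macrophage RNA in droplets with T cells. Median depths before thinning were 3303, 2431, 3080 and 3005 UMIs in T cell-like cells of the control and NASH libraries, and 3209, 2857, 8292 and 7620 in the macrophage-like cells used. The B cell-like class, named in advance as the background, had a Trem2 UMI in 19.6% ± 3.68, a Cd9 UMI in 17.5% ± 9.76 and a Gpnmb UMI in 10.97% ± 6.49 of its NASH cells. Its medians were 5164 and 5208 UMIs in the NASH libraries.

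**Figure D4:**
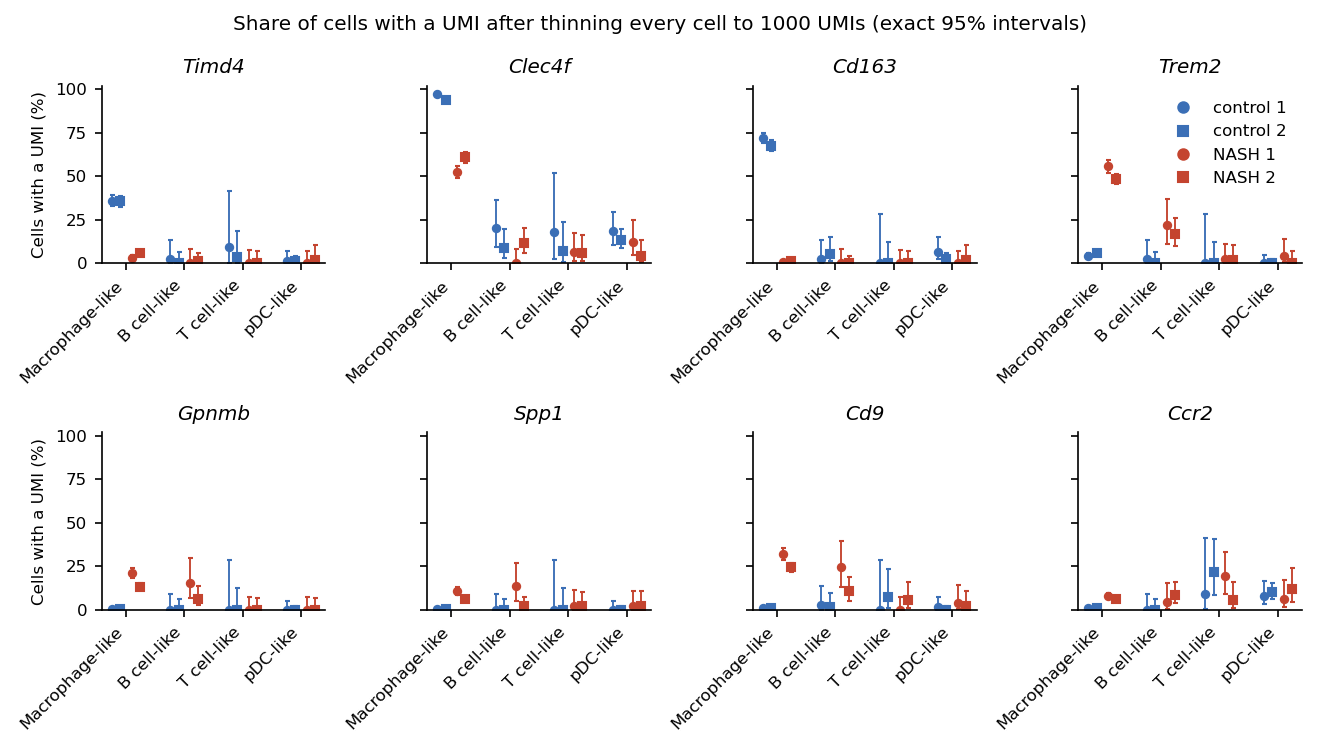
Share of cells with a UMI of each of 8 genes (percent, vertical axes) after thinning every cell to 1000 UMIs, in 4 classes of the 2 control (blue) and 2 NASH (red) libraries, with exact Clopper-Pearson 95% intervals as bars (pDC, plasmacytoid dendritic cell). Macrophage-like cells with a Trem2 UMI were 4.21% and 5.91% in the control and 55.7% and 48.5% in the NASH libraries.

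Kupffer-like cells, the macrophage-like clusters in which at least 80% of cells had a UMI of Clec4f and of Vsig4, were compared between the diets (975, 843, 430 and 630 cells). Within this class too Trem2 rose, from 44.2 ± 1.06 to 823 ± 37.7 CPM (mean ± SD, n = 2; log2 4.22, SE 0.164), Cd9 from 8.33 to 312 CPM (log2 5.21) and Mmp12 from 14.1 ± 2.19 to 1064 ± 80.7 CPM (log2 6.24). Cd163 fell from 1319 to 11.4 CPM (log2 -6.81, SE 0.359), Timd4 from 430 to 100 CPM (-2.10) and C2 by 5.20 on the log2 scale. Gpnmb had 3 control UMIs, a NASH to control ratio of 309 (95% counting interval 105 to 1498), and Spp1 rose by 5.26 (SE 1.05). Of 9781 genes tested 3779 changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2028 higher and 1751 lower. In that edgeR test the adjusted p was 2.15e-07 for Trem2, 1.66e-06 for Cd9, 5.36e-05 for Cd163, 0.000228 for Timd4, 0.000107 for Gpnmb and 0.0370 for Spp1. The same Marco-led and Fkbp5-led clusters held most control cells of this class, and the Folr2-led and Mmp13-led clusters most NASH cells. Genes of the selection, Clec4f and Vsig4, are not results here. Selection on their RNA cannot tell resident Kupffer cells from recruited macrophages that carry these transcripts. A change within resident cells was thus not separated from a change in which cells made up the class.

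In Kupffer-like sums 23 of 25 members of the lipid- and scar-associated list rose and none fell (23 over the list alone), at camera adjusted p = 1.07e-16 and adjusted p = 0.362 with an estimated correlation. The Kupffer identity list is not given here, since the class was selected on its genes. Interferon-stimulated genes (19 of 26 higher, adjusted p = 1.48e-07), MHC class II genes (11 of 15 higher, 5.48e-05), oxidative phosphorylation (27 of 29 higher, 1.30e-12) and hepatocyte transcripts (12 of 15 lower, 3.34e-07) passed camera with the signs seen in the whole class, at adjusted p = 0.628, 0.567, 0.359 and 0.567 with an estimated correlation. The calls of Gpnmb, Gdf3, Spp1, Fabp5 and Alb were lost without either control library. The number of changed genes was 1947 without NASH library 2, 2463 without NASH library 1 and 2179 with DESeq2.

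In B cell-like cells (41, 56, 45 and 94 cells) the genes that differed most were macrophage genes. Gpnmb and Mmp12 had 0 UMIs in the control and 188 and 178 in the NASH libraries, at least 23.4-fold and 22.1-fold higher against a floor of 3 counts over the control group. Ms4a6d, Ptafr and Tbxas1 were at least 9.20-fold, 6.34-fold and 6.34-fold higher. Jchain, the joining chain of secreted antibody, fell from 136 ± 48.0 to 20.1 ± 14.1 CPM (n = 2; log2 -2.56, SE 0.424), and Vpreb3, a gene of B cell development, from 218 ± 112 to 45.4 ± 16.2 CPM (-2.20, SE 0.371). Fcna (-3.10) and Ptprb (-2.29) also fell, and Marco had 25 control and 3 NASH UMIs, a control to NASH ratio of 22.3 (95% counting interval 6.82 to 116). Of 2652 genes tested 425 changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 243 higher and 182 lower. EdgeR's adjusted p was 0.000535 for Gpnmb, 0.000246 for Mmp12, 0.000537 for Jchain and 0.000840 for Vpreb3. The lipid- and scar-associated macrophage list rose (17 of 22 members, 18 over the list alone; camera adjusted p = 5.04e-16), as did macrophage RNA (7 higher and 1 lower of 11; 1.79e-05) and lysosome genes (13 of 22; 2.59e-08), while B cell RNA fell (4 of 7 lower; 3.20e-05). With an estimated correlation their adjusted p was 0.262, 0.279, 0.262 and 0.262.

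At least 5 C1q UMIs per 1000, a macrophage signal, were carried by 25.2% (exact 95% interval 18.2 to 33.2%) of NASH and 3.16% (0.656 to 8.95%) of control B cell-like cells. With no removal of putative doublets and at Leiden resolution 2.0 the class held a different set of cells. The log2 ratio of its shares was -0.49 and -0.45 there, against 0.164 in the main setting, and 42 of 1617 and 35 of 1632 genes changed. Without the cells that carried the C1q signal 115 of 1712 genes changed. The number was 199 in DESeq2, 277 without NASH library 1 and 267 without NASH library 2. The count thus depended on these settings and on each NASH library.

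In T cell-like cells (11, 28, 47 and 52 cells) Ly6c2, carried by memory and effector CD8 T cells, rose from 110 ± 61.2 to 747 ± 74.7 CPM (mean ± SD, n = 2; log2 2.66, SE 0.352). Cd8b1, a chain of the CD8 coreceptor, had 2 control and 106 NASH UMIs, a ratio of 18.5 (95% counting interval 5.01 to 155), and Cst7 (cystatin F) 1 and 43, a ratio of 15.0 (2.56 to 608). The MHC class II genes H2-Eb1 and H2-Aa rose by 2.42 each on the log2 scale. Macrophage transcripts moved beside them, with Apoe higher (991 to 2880 CPM, log2 1.56, adjusted p = 0.000632 in edgeR's test) and Lyz2 short of the threshold (1.26, 0.0597). The macrophage RNA list did not pass there (1 of 7 higher, camera adjusted p = 0.159), nor did it in macrophage-like sums. It mixes genes that rose in NASH macrophage-like cells (Apoe) with genes that fell there (Clec4f, here at log2 -1.20 and short of the threshold). This miss thus cannot argue against carried-over macrophage RNA. Wfdc17 fell by 2.04, the proliferation-linked Hmgb2 by 0.99, AY036118 by 1.32 and Wdr89 by 1.18. Of 1688 genes tested 23 changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 higher and 16 lower. Unnamed cluster 18, C1q-high and led by T cell genes, gave no cells to these sums. EdgeR's adjusted p was 0.000632 for Ly6c2, 0.00369 for Cd8b1, 0.0397 for Cst7, 0.00585 for H2-Aa and 0.0227 for Wfdc17 and for Hmgb2. The MHC class II list rose (3 of 5 members; camera adjusted p = 2.03e-07), the T and NK effector list passed with 0 of 10 members past the threshold (0.0247), and the cell cycle list fell (1 of 9 lower; 0.00235), at adjusted p = 0.633, 0.815 and 0.812 with an estimated correlation. In edgeR's test no gene passed without control library 1 or without control library 2, where 150 and 205 genes had an unadjusted p under 0.05, and 13 genes passed without NASH library 2.

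Whether the diet effect differed between macrophage-like and monocyte-like cells was tested as an interaction, with each library as a block. CPM in this fit were scaled over both classes together, so they differ somewhat from those of the macrophage-like fit above. Ccr2 had the smallest p, with 13.6 and 12.2 CPM in control and 114 and 97.8 CPM in NASH macrophage-like sums against 667 and 836, and 864 and 806 CPM, in monocyte-like sums, a log2 interaction of 2.91 (SE 0.324). S100a11 (2.65), Tmsb10 (2.47), Lgals1, a galectin (2.82), Sirpb1c (2.80) and Anxa2 (2.36) also had the more positive diet effect in macrophage-like cells. Marcksl1 (-4.30) and Hmox1, the heme-degrading enzyme (-4.21), had the more negative one. Marcksl1 was spread in the controls, at 279 and 975 CPM in macrophage-like and 0 and 74.6 CPM in monocyte-like sums. Of 9352 genes tested 126 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 48 more positive and 78 more negative in macrophage-like cells, with adjusted p from 3.28e-15 for Ccr2 to 1.02e-09 for Anxa2. The control monocyte-like sums came from 4 and 11 cells, in control library 1 fewer than the minimum of 10 set for tests within a class, so the monocyte side of each control value is thin.

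The interaction depended on scaling and on single libraries. The median over all genes tested was -0.78 on the log2 scale, and -0.27 with upper-quartile factors. Without control library 2, which leaves the sum of 4 control monocyte-like cells, that median was -6.51. Relative to the median of -0.78 the interaction was 3.69 for Ccr2, 3.44 for S100a11, -3.52 for Marcksl1 and -3.43 for Hmox1. The split of more positive and more negative genes was 48 and 78 at first, 237 and 45 with upper-quartile factors, 40 and 23 in DESeq2 and 130 and 57 without control library 1. The count was 62 without control library 2, 13 without NASH library 1 and 12 without NASH library 2.

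Monocyte-like, dendritic cell-like, neutrophil-like and NK cell or ILC1-like cells numbered fewer than 10 in at least 1 control library (4, 9, 5 and 6 in control library 1), so the test within the class fixed for them was not run.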

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

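The test of deeper sequencing through plasmacytoid dendritic cell-like cells was chosen after the result was seen.

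The diet effect differed between macrophage-like and monocyte-like cells in 126 genes, with Ccr2, S100a11 and Marcksl1 at the smallest p, in the interaction test of edgeR with Benjamini-Hochberg adjustment, and this difference between groups is why it is listed here. The control monocyte-like sums held 4 and 11 cells, and a change in the mix of macrophage-like clusters was not separated from this difference.

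A signal in cells outside every class is the other result. Unnamed cluster 18, with 170 cells, had a mean share of 4.51% ± 0.905 in the NASH and 0.623% ± 0.0154 in the control libraries (n = 2). It was led by the T cell genes Cd247, Bcl11b, Cd3d and Lck and had C1q UMIs in at least 90% of its cells, so the naming rule left it out. Its median was 10071 and 9570.5 UMIs in the NASH libraries, against 3080 and 3005 in T cell-like and 8292 and 7620 in macrophage-like cells. What these droplets held was not tested.

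Macrophage-like cells carried 2.64 times as many UMIs (ratio of medians) in the NASH as in the control libraries. Deeper sequencing or capture of the NASH libraries as the whole cause is argued against by plasmacytoid dendritic cell-like (ratio 1.07) and T cell-like cells (1.06). The ratio was 0.855 in dendritic cell-like and 0.993 in stellate or fibroblast-like cells. It was, however, 2.73 in neutrophil-like cells, with 5 and 11 control cells, and 3.35 in cycling cells, a C1q-high cluster. Between these lay monocyte-like (1.255), plasma cell-like (1.41), NK cell or ILC1-like (1.45), B cell-like (1.70) and endothelial-like cells (1.85). The cell filters are argued against by the ratio of 3.12 with all deposited cells. A cell state with more RNA is argued against by control cells in the clusters of most NASH cells, which had 0.713 and 0.916 times the UMIs of the other control macrophage-like cells, although this ratio was 1.04 and 2.52 in the NASH libraries, from 5 and 7 cells outside these clusters. Damage to control macrophages, whose median mitochondrial share was 6.32% and 6.23% against 3.59% and 3.25%, was not tested, and the values go both ways. Control cells in the NASH clusters had 2.25% and 3.09% at 2281.5 and 2612.5 UMIs. The 5 and 7 cells outside these clusters in NASH libraries 1 and 2 had 6.64% and 8.34% at 7962 and 3045 UMIs. Damage and an effect of the diet on RNA content are hypotheses that were not tested.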

How the results depend on the processing

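The tests with all deposited cells, without the Mmp13-led cluster and without B cell-like cells with the C1q signal were chosen after the result was seen. Of 1098 alternative values of 65 genes named in macrophage-like cells, 1062 kept direction and side of the threshold, 23 lost and 8 gained the call and 5 reversed. In Kupffer-like cells 368 of 383 kept both, in B cell-like 104 of 114, in T cell-like 69 of 121 and for the interaction 97 of 104. Class shares kept both in 134 of 173, lost the call in 19, gained it in 12 and reversed in 8, of 24 shares of cells with a UMI 19 moved by more than 1 SD, and 92 of 110 list results held. Macrophage-like genes changed numbered 2965 with DESeq2, 2582 with the stricter cell filter and 2306 when thinned with equal cells, Kupffer-like genes 2179, 1880 and 1394, and 1947 to 3587 with 1 library left out. B cell-like genes numbered 199 with DESeq2, 246 with at least 50 counts, 42 with no doublet removal, 35 at resolution 2.0, 78 thinned, 218 with all deposited cells, 115 without the C1q signal and 267 to 452 with 1 library left out. T cell-like genes numbered 15 with DESeq2, 2 with no filter on low counts, 220 at resolution 0.5, 189 cell by cell, 49 with all deposited cells, 0 to 22 with 1 library left out, and 0 thinned in edgeR (18 at an unadjusted p under 0.05). The interaction gave 63 genes with DESeq2, 282 with upper-quartile factors, 46 with the stricter cell filter, 238 with all deposited cells and 12 to 187 with 1 library left out. Of the class shares 10 passed cell by cell, of which 8 are among the 14 classes and the others are eosinophil-like and platelet-like cells, and 0 to 1 with 1 library left out, and of the macrophage-like lists 7 passed with fry and 0 with an estimated correlation. Reversed were Clec4f cell by cell (log2 0.0563), Ly6c2 in macrophage-like cells at resolution 0.5 (-0.0852) and 2.0 (-0.73), cell by cell (-0.39) and with all deposited cells (-0.42), and Wfdc17 in T cell-like cells at resolution 0.5 (0.0116) and cell by cell (0.70). The log2 ratio of B cell-like shares reversed to -0.49 with no doublet removal, -0.47 with 3 times as many removed, -0.78 with the stricter cell filter, -0.45 at resolution 2.0 and -0.44 with the other denominator, and ran from -0.31 to 0.51 with 1 library left out. With that denominator cycling shares were at -0.39, and plasma cell-like shares were at 0.56 cell by cell. With 1 library left out the lone sample of its diet is assumed to vary like the others. In each case the cause was not tested.

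Same-numbered libraries did not deviate together from their diet means. The correlation of deviations was -0.0332 in macrophage-like, 0.0633 in B cell-like and -0.0203 in T cell-like sums. This cannot show whether they shared a day, which the labels do not state. With the replicate number as a block, 38 T cell-like genes and 1 class share passed, and the adjusted p was 0.0658 for dendritic cell-like, 0.110 for cholangiocyte-like and 0.333 for plasmacytoid dendritic cell-like shares. Not run were the interaction at resolution 0.5 (no monocyte-like class) and thinned (too few monocyte-like cells), Kupffer-like cells cell by cell, T cell-like cells under the stricter filter (fewer than 10 cells) and most alternatives of the untested classes.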

Other observations

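The tests in classes and libraries added here, and the test of heme uptake without cluster-leading genes, were chosen after the result was seen.

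Endothelial-like cells that passed the sort (55, 121, 61 and 43 cells) were tested in the same way. Mt2, a metallothionein, fell from 507 ± 82.5 to 39.9 ± 10.1 CPM (n = 2; log2 -3.71, SE 0.292) and Cyp26b1, which breaks down retinoic acid, from 323 ± 104 to 27.8 ± 3.06 CPM (-3.52). Spp1 and Igfbp5 had 0 control UMIs and were at least 14.8-fold and 11.1-fold higher, and the macrophage gene Trem2 rose from 15.97 to 269.7 CPM (4.24). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 464 of 4508 genes changed, 208 higher and 256 lower, and 264 without NASH library 1, 189 with DESeq2 and 127 when thinned. In plasmacytoid dendritic cell-like cells 85 of 3539 changed, 11 higher and 74 lower, with Jchain (log2 -2.63) and Sorl1 (-1.83) lower. The Kupffer cell genes Fcna (-3.09), C6 (-4.26), Clec4f (-1.56) and Hmox1 (-1.74) fell in the same sums. With cells assigned one at a time 399 genes changed in this class, 215 higher and 184 lower. In cycling cells, a cluster with C1q UMIs in at least 90% of cells, 1339 of 6586 changed, 731 higher and 608 lower, with Mmp12 (5.48) and Cx3cr1 (4.06) higher and Cd163 (-8.15) and Timd4 (-3.28) lower. That count was 764 without NASH library 1, 757 without NASH library 2, 474 with DESeq2 and 230 when thinned.

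With fewer than 10 cells allowed, Spp1 and Cd63 had 0 UMIs in the 15 control monocyte-like cells and were at least 15.9-fold and 11.7-fold higher in NASH. In dendritic cell-like cells Ccl22, a chemokine of mature dendritic cells, rose from 24.2 ± 34.2 to 373 ± 15.2 CPM (log2 3.58), and the Ccr7-led cluster held 0, 4, 54 and 43 cells. In NK cell or ILC1-like cells the chemokine Xcl1 rose from 1146 ± 116 to 2783 ± 369 CPM (1.31). EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 150 of 4569 genes in monocyte-like, 117 of 6078 in dendritic cell-like, 49 of 952 in neutrophil-like and 35 of 1094 in NK cell or ILC1-like cells. Other settings that gave at least 10 cells called 270 dendritic cell-like genes (resolution 0.5), 234 neutrophil-like genes (no doublet removal) and 217 NK cell or ILC1-like genes (cell by cell, 138 higher and 79 lower, against 10 and 25).

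Macrophage genes appeared in NASH B cell-like cells. Free RNA in the droplets as the source of a signal of at least 5 C1q UMIs per 1000 is argued against. In the NASH libraries such a signal was carried by 25.2% (exact 95% interval 18.2 to 33.2%) of B cell-like cells. The share was 1% (0.0253 to 5.45%) in plasmacytoid dendritic cell-like cells. It was 3.03% (0.629 to 8.601%) in T cell-like cells, but class assignment may have set this value, so it cannot decide. Unnamed cluster 18, C1q-high and led by T cell genes, was kept out of that class and held 81 and 72 NASH cells. The cut of 5 C1q UMIs per 1000 cannot see free RNA at lower levels. Among cells without the signal, 3.125% (0.649 to 8.86%) of NASH T cell-like and 4.04% (1.11 to 10.02%) of NASH plasmacytoid dendritic cell-like cells had a Trem2 UMI. In both control classes the share was 0%. Droplets holding a B cell and a macrophage may account for the macrophage genes, since B cell-like cells with the C1q signal had 2.44 and 2.69 times the median UMIs of the others. Expression by B cells cannot be told apart from the rest, since 7.69% (3.38 to 14.6%) of the B cell-like cells without the signal had a Trem2 UMI, an interval that spans both bounds set for this test.

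The 2 control libraries differed in Kupffer-like cells, with Hmox1 at 1673 and 4189 CPM and Fos at 531 and 299 CPM. For glucocorticoid exposure, a response list lay at percentile 97.9 of random lists there, with 12 of 15 members higher in control 1. It lay at 81.0 in plasmacytoid dendritic cell-like and 53.0 in endothelial-like cells, short of the bound set for this test. Only 7 and 11 members were measured in those 2 classes, and the list left out the genes seen beforehand, so the test cannot decide. Stress during tissue handling may contribute, since the immediate-early list lay at percentile 100 in Kupffer-like, 100 in endothelial-like, 96.4 in plasmacytoid dendritic cell-like and 81.1 in B cell-like cells. Its heat shock members went the other way in Kupffer-like cells (Hsph1 -1.22, Hspa1b -0.98, Hspa1a -0.60, control 1 minus control 2, log2), and the NF-kB list lay at percentile 0 there but at 99.96 in endothelial-like cells, while hepatocyte transcripts were higher in control 1 in plasmacytoid dendritic cell-like cells (12 of 12, median 3.06). Uptake of red cells or heme, more in control library 2, may contribute as well. The iron and heme list without cluster-leading genes lay at percentile 1.29, with 3 of 10 members higher in control 1. The random lists were drawn gene by gene, so they do not cover genes that vary together. The Marco-led cluster, which Hmox1 also led, held 158 and 718 cells of the control libraries 1 and 2. A difference between the mice was not tested.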
